A study of Homo sapiens with 6 samples.

How the data were processed

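Poly(A) RNA of MG63 cells was sequenced in 6 libraries, 3 shNC and 3 shFTO, prepared from TRIzol extracts on a strand-specific protocol and run on an Illumina NovaSeq, per the labels. Per the submitters' processing notes the tools were FastQC 0.10.1, HISAT2 2.2.1, HTSeq 0.6.1, StringTie 1.3.3b and DESeq2 1.50.2, with the human genome build GRCh38. The order of these steps and the strand setting of the counting are not given in the sources used here. The deposited values are FPKM per gene, rounded to 2 decimals, with exonic length, position, strand and symbol for each Ensembl gene ID. FPKM divides reads by exonic length and by the library's total, so a few very abundant genes lower the value of all others, and at this depth the rounded values still stand for whole reads.

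Columns of the control group carried NC and a number, and columns of the knockdown group carried sh and a number. They were matched to shNC and shFTO replicates 1 to 3 by those names. Gene types came from GENCODE release 29 on the same build, in which 94.3% of gene IDs were found. Of those found, 99.9% were on the same chromosome and strand.

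FPKM multiplied by length summed to the same constant in each column, so a library total was searched between 20000 and 200000 reads at which FPKM times length gave whole reads. At the totals found, 100% of values above 0 were whole within 0.05 read in every library. The recovered totals ran from 93629 to 106246 reads, 592760 over the 6 libraries. Between 3208 and 3435 genes had at least 1 read in a library, and 705 genes had at least 10 reads per library on average. A count of 0 was given an upper limit of 3 reads.

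The planned test assumed deposited gene counts. As FPKM was held, the fallback fixed at the same time was used: limma 3.58.1 in R 4.3.3, with trend and robust moderation, on log2(FPKM + 1), for 4932 genes with a mean of at least 1 FPKM in one group. The model held the group only. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05, and a second count asked for a 2-fold change. Fold changes on log2(FPKM + 1) understate the change of genes near or under 1 FPKM. Where some libraries are at 0 and 1 read is worth many FPKM, they can instead exceed the ratio of the group means, as for RPS12, with means of 5.57 and 41.1 FPKM and a log2 fold change of 3.94. The 40 gene lists were fixed before the data were examined. Lists with at least 3 tested genes, 33 in all, were tested with camera at a preset correlation of 0.01. Summed reads of lists, library shares and numbers of detected genes were compared by exact two-sided permutation of 3 against 3 with SciPy 1.17.1 under Python 3.11.15.

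Genes were named by a rule fixed before the data were examined. It took FTO, then called genes with a mean of at least 1 FPKM and groups that do not overlap (up to 8 with the largest rise, 8 with the largest fall, and 4 of each direction with the smallest p), then up to 3 tested genes with the smallest p in each list. The genes with the most reads, usual reference genes, further members of the fixed lists and the genes with the smallest p or the highest and lowest estimates in the fit to recovered reads were named after their values were seen. Some genes that the rule takes are not reported here.

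Alternatives planned before the data were examined were a pseudocount of 0.1, no filter, a mean of at least 5 CPM, limma-voom, a replicate block, an adjusted p under 0.01, a test against a 1.2-fold change, each library left out in turn, and for lists an estimated correlation and fry. Alternatives chosen after seeing the data were median-of-ratios and upper-quartile scaling of FPKM, a filter of at least 10 reads per library, a quasi-Poisson fit to recovered reads, and summed reads of a list without its most-read gene. That fit used genes with at least 30 reads, with a moderated dispersion whose median was 1.52. The comparison of library pairs by chi-square was also chosen then.

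The tests were run on simulated data with 200 changed genes per simulation and 5 simulations per fold size, drawn at the real depths. Every gene was given the same dispersion of 1.52, the form that the fit to recovered reads assumes. Recovery by that fit is thus a favourable case. For shFTO against shNC, limma found 3.9% of genes changed 2-fold, 13.1% of those changed 4-fold and 20.8% of those changed 8-fold, with 2.4, 2.8 and 6.2 false calls per simulation. Of simulated genes with at least 10 reads per library it found 26.8%, 77.9% and 95.8%. The fit to recovered reads found 66.7% of these at 2-fold and 100% at 4-fold, with 0.4 and 2.6 false calls per simulation. Of simulated genes with at least 100 reads per library, limma found 86.2% of those changed 2-fold and the fit to recovered reads 100%. Most genes had far fewer reads. The p-values set the group difference against the spread between the 3 libraries of each group, which single reads can shape where reads are few.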

Results

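RNA sequencing was done on MG63 cells, an established human osteosarcoma line with fibroblast-like, bone-forming lineage traits. The design compared cells carrying a stable short hairpin against FTO (shFTO) with cells carrying a control hairpin (shNC), and asked which transcripts depend on FTO. FTO encodes an RNA demethylase that removes the methyl group from N6-methyladenosine (m6A), a common internal mark of messenger RNA. Each group held 3 biological replicates, so the values below are means ± SD with n = 3 per group unless stated. Expression was given as FPKM, and the whole reads behind each value could be recovered. They came to 94349, 100992 and 93629 reads in shNC replicates 1, 2 and 3, and to 106246, 94083 and 103461 in shFTO replicates 1, 2 and 3. Of 61806 genes listed, 54749 were at 0 in all 6 libraries and 1373 were above 0 in all 6.

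FTO (ENSG00000140718, GRCh38 chromosome 16, 53701692 to 54158512, plus strand) was listed at 0 FPKM in all 6 libraries, the 3 control libraries included. At 3 reads, the upper limit that a count of 0 allows, FTO would stand at 1.49, 1.39 and 1.5 FPKM in shNC replicates 1, 2 and 3. The limits were 1.32, 1.49 and 1.36 FPKM in shFTO replicates 1, 2 and 3. Over the 3 libraries of a group together the limit was 0.486 FPKM for shNC and 0.462 FPKM for shFTO. A lower level of FTO in shFTO could therefore not be seen in these values, and the labels could not be checked on the targeted gene. Whether depth or another cause left FTO at 0 in the controls was not tested. These limits cover counting error only.

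EIF4G2, a translation initiation factor gene (chromosome 11, 10797050 to 10808940), had the most reads. It stood at 10420 ± 327 FPKM in shNC and 10120 ± 450 in shFTO, and held 8.7% of all recovered reads. EIF1, which helps select the start codon, had 9210 ± 511 and 8652 ± 221 FPKM. YBX1, an RNA-packaging protein, had 6634 ± 124 and 6532 ± 137 FPKM, and EIF5A, an elongation factor, had 5924 ± 438 and 5605 ± 242. Among the 20 genes with the most reads, 5 had names starting with EIF and 5 were HNRNP genes, which encode RNA-binding proteins of the nucleus. The RNA helicases DDX3X and DDX5 and the poly(A)-binding protein gene PABPC1 were also among them, as were UBE2D3, a ubiquitin-conjugating enzyme gene, SERF2, the nuclear import gene KPNA4 and the chromatin gene HMGB1. The 10 genes with the most reads held 31.8% of all reads, 34 genes held 50% and 513 genes held 90%. Reads of HNRNPA3 and of its pseudogene HNRNPA3P6 (1979 reads) are uncertain, since near-identical copies can share reads.

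Among genes often used as references, reads varied widely. RPLP0, a ribosomal stalk protein gene, had 1466 reads over the 6 libraries and EEF1A1, a translation elongation factor gene, had 841. GAPDH, a glycolytic enzyme gene, had 57.8 ± 0.233 FPKM in shNC and 65.2 ± 24.5 in shFTO, from 88 reads. ACTB, encoding cytoplasmic actin, had 75 reads, the intermediate filament gene VIM had 85 reads and the general transcription factor gene TBP had 1 read. Among 50 cytosolic ribosomal protein genes, the 90th percentile of mean FPKM was 51.9 and the 10th percentile 1.91. Some transcripts of the mesenchymal and bone lineage had reads. COL1A1, encoding a chain of fibrillar collagen, had 139 reads, SPARC, encoding the bone matrix protein osteonectin, had 121, and the lineage transcription factor gene TWIST1 had 69. RUNX2, the master regulator of osteoblasts, had 14 reads, while ALPL, BGLAP and SPP1 were listed at 0 in every library. Of the marker lists for other cell types, the chondrocyte, adipocyte and blood cell lists had no reads and the endothelial list had 1 read. Reads were found for 2 of 17 epithelial, 3 of 18 neural and 5 of 17 muscle genes.

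**Figure D1:**
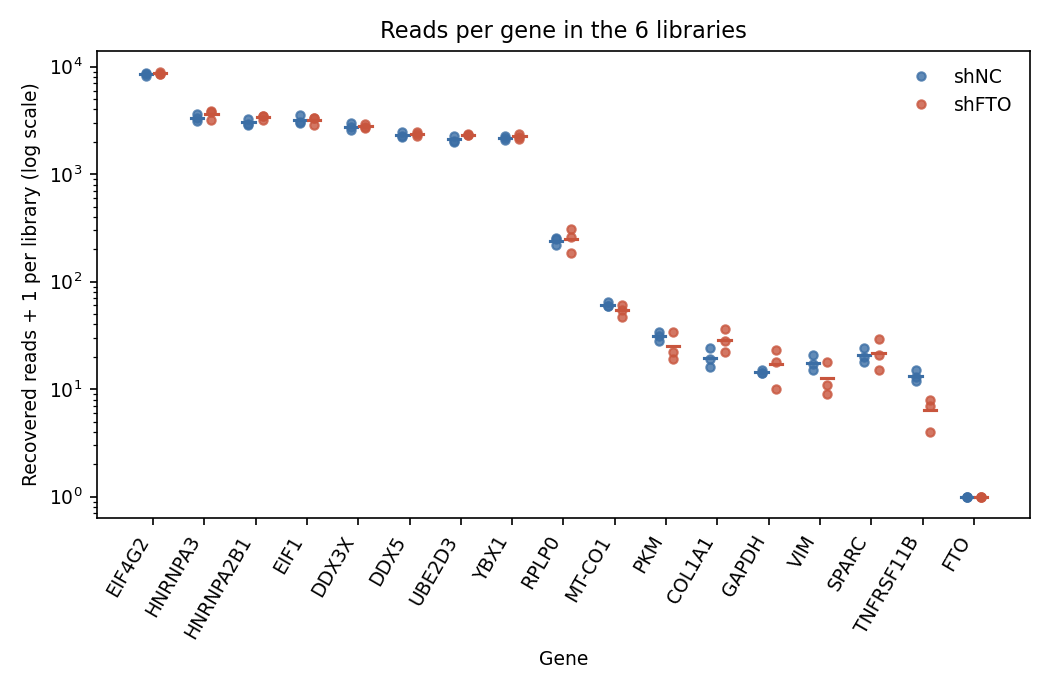
Recovered reads plus 1 per library on a log axis, for the 8 genes with the most reads, for 8 genes of ribosomes, mitochondria, metabolism and the mesenchymal lineage, and for FTO. Points are the 3 libraries of each group, short bars are group means, and FTO sits at 0 reads in all 6 libraries.

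The comparison of shFTO with shNC called 2 genes, both processed pseudogenes with fewer reads in shFTO. ENSAP2, a pseudogene of the phosphatase inhibitor gene ENSA (chromosome 14, 82692704 to 82693055), had 49.6 ± 35.3 FPKM in shNC and was at 0 in all 3 shFTO libraries. These values came from 5 reads against 0, with 3, 1 and 1 reads in shNC replicates 1, 2 and 3. With shFTO set at 3 reads over the group and the 5 taken as exact, ENSAP2 would be 1.75-fold lower. This leaves out the counting error of the 5 reads, so it is not a lower bound. H3P47, a histone H3 pseudogene (X chromosome, 123514473 to 123514872), fell from 95.8 ± 56.8 to 24.8 ± 1.6 FPKM, or 11 reads against 3. These were 2, 3 and 6 reads in shNC replicates 1, 2 and 3, and 1 read in each shFTO library. The SD in shFTO thus reflects library size alone and leaves out counting error, and the limma SE and p draw on it. The ratio of H3P47 reads, scaled to library size, was 0.259 with an exact 95% interval from 0.0465 to 0.982. That interval covers counting error only and is too narrow for libraries that differ by more than that. In limma on log2(FPKM + 1) over 4932 genes, ENSAP2 had a log2 fold change of -5.45 (SE 0.75, adjusted p = 7.86e-05) and H3P47 of -1.76 (SE 0.34, adjusted p = 0.0259). Both were lower in 3 of 3 shFTO libraries than in any shNC library, a separation that chance gives to 10% of genes with 3 against 3. Both fitted changes were past 2-fold, while 5 reads against 0 set no firm lower limit for ENSAP2 and the interval for H3P47 also allows smaller changes. No gene was called higher.

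Leaving out 1 library ended both calls. Without shNC replicate 1, ENSAP2 had a log2 fold change of -4.92 and a limma adjusted p of 0.113. Without shNC replicate 3 or shFTO replicates 1, 2 or 3, H3P47 had log2 fold changes of -1.31, -1.72, -1.81 and -1.74 and limma adjusted p values of 0.284, 0.217, 0.386 and 0.312. Limma-voom on recovered reads called neither, with log2 fold changes of -2.06 for ENSAP2 (adjusted p = 0.643) and -1.42 for H3P47 (adjusted p = 0.794). The fitted change of ENSAP2 depended on the pseudocount and was -8.74 with 0.1. Without 1 library, genes were also called higher: the count of called genes rose to 9 without shNC replicate 2 (6 higher and 3 lower), to 7 without shNC replicate 3 (5 higher and 2 lower) and to 8 without shFTO replicate 1 (4 higher and 4 lower). It rose to 4 (2 higher and 2 lower) with upper-quartile scaling. Over all 4932 genes, 190 had an unadjusted p under 0.05, against 247 given by chance.

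**Figure D2:**
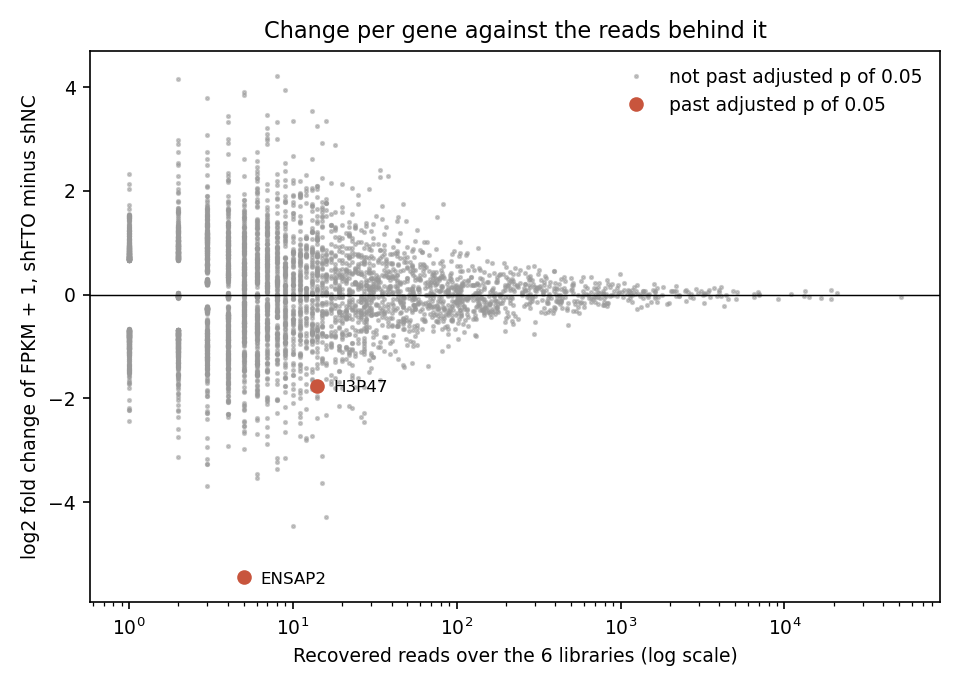
Log2 fold change of FPKM + 1 (shFTO minus shNC) for each of 4932 tested genes against its recovered reads over the 6 libraries, on a log axis. The larger points are ENSAP2 with 5 reads and H3P47 with 14, and the spread of the other genes narrows as reads increase.

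The more reads genes had, the closer to 0 their estimates lay, with a median absolute log2 change of 0.07 at 100 or more reads per library and 0.17 at 10 or more. Of 150 genes with at least 100 reads per library on average, SON, encoding a splicing cofactor, had the highest estimate, a log2 change of 0.40 in the quasi-Poisson fit to recovered reads. RAP1B, encoding a small GTPase, had the lowest, at -0.28. Over the 705 genes with at least 10 reads per library, estimates ran from -1.31 for CDV3, with 47 and 20 reads, to 1.58 for ATXN7L3, with 20 and 63 reads, neither of them called. The 95% interval of the change excluded a 2-fold difference for all 150 of these genes, and for 72.3% of the 705. That fit called 0 of 1021 genes, with 60 at an unadjusted p under 0.05 against 51 by chance. Its smallest adjusted p, 0.203, was shared by CPEB2, ATXN7L3, TMED2, EIF3J, EIF1, HNRNPA2B1 and SON, named here, like RAP1B and CDV3, after their values were seen. EIF3J, a translation initiation factor, had 313 ± 67 FPKM in shNC and 207 ± 17.1 in shFTO, and TMED2, a cargo receptor of early secretion, had 166 ± 17.3 and 97.5 ± 11.8. In limma on genes with at least 10 reads per library, 0 of 705 genes were called and 31 had an unadjusted p under 0.05, against 35 by chance.

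Reads of the m6A machinery were uneven. Of 31 genes that write, erase or read m6A, 30 had reads, 12 had at least 10 reads per library, 25 were tested, and 0 rose and 0 fell in limma. HNRNPA2B1, a nuclear m6A reader, had 2493 ± 74.8 FPKM in shNC and 2657 ± 37.5 in shFTO (log2 fold change 0.09, SE 0.06, limma adjusted p = 0.772). In the fit to recovered reads HNRNPA2B1 had an adjusted p of 0.0166 when adjusted over the list alone and 0.203 over all genes, at a log2 change of 0.09 (SE 0.03). WTAP, a subunit of the methyltransferase complex, had 100.5 ± 14.8 and 125 ± 30.2 FPKM, and FXR1, an RNA-binding reader, had 293 ± 12 and 257 ± 11.2. The reader genes YTHDF2, YTHDF3 and YTHDC1 had 526, 982 and 598 reads over the 6 libraries, while the catalytic METTL3 had 1, METTL14 had 2 and the other demethylase gene, ALKBH5, had 4. The list made up 4460 ± 96.1 of 100000 reads in shNC and 4637 ± 105 in shFTO (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). HNRNPA2B1 held 19270 of its 26970 reads, and without it the list had 1316 ± 2.67 and 1286 ± 90.7 (exact p = 0.7). Genes next to FTO at 16q12.2 had 20 reads in shNC and 40 in shFTO over 10 genes, or 7.03 ± 5.15 and 13 ± 4.7 of 100000 reads (exact two-sided permutation p = 0.3, adjusted p = 0.847 over 36 lists). Among them CHD9, a chromatin remodeller gene, had 10 and 12 reads, 8 of the 10 in shNC replicate 3. RPGRIP1L had 4 and 10 reads. MMP2, encoding a matrix metalloproteinase, had 2 and 11, the 2 both in shNC replicate 1. Among 30 genes linked to FTO in earlier work, 14 had reads and 0 of 13 tested were called. The transcription factor gene JUNB had 0 and 8 reads, the mitophagy receptor gene BNIP3 had 7 and 1, and MYC had 0 and 2.

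In the osteoblast lineage list, 12 of 42 genes could be tested, and point estimates were higher in shFTO for 8 and lower for 4. The list had 110 ± 9.7 of 100000 reads in shNC and 126 ± 13.65 in shFTO (exact two-sided permutation p = 0.3). Without ALCAM, its most-read gene, it had 83.7 ± 6.61 and 101.5 ± 11.55 (exact p = 0.1). In fry the list was higher in shFTO at an unadjusted p of 0.0223 (adjusted p = 0.447). Adjusted over all genes 0 list members were called, while 1 was called over the list alone. That gene was TNFRSF11B, encoding osteoprotegerin, the decoy receptor that restrains osteoclast formation. It had 51.2 ± 8.09 FPKM in shNC and 20.7 ± 7.29 in shFTO, from 37 and 16 reads, and was lower in 3 of 3 shFTO libraries. Its log2 fold change was -1.32 (SE 0.36), with a limma adjusted p of 0.379 over all genes and 0.011 over the list alone. The call over the list alone was lost without shNC replicate 1, shNC replicate 3 or shFTO replicate 2 (limma adjusted p = 0.0562, 0.0832 and 0.0716). The log2 fold changes there were -1.318, -1.203 and -1.015. The call was also lost in limma-voom (adjusted p = 0.0787, log2 fold change -1.253) and in the fit to recovered reads (adjusted p = 0.13 over 6 list genes, log2 change -1.28, SE 0.58). In the same list ATF4, a transcription factor of the amino acid response, had 1 and 8 reads. Collagen and basement membrane genes gave 0 calls among 26 tested: COL1A1 had 21.6 ± 5.3 and 30.7 ± 9.62 FPKM (limma adjusted p = 0.772), and the proteoglycan gene BGN had 21.3 ± 12.1 and 39.1 ± 21.4. Genes of mesenchymal transition and invasion gave 0 calls among 22 tested, and S100A4, EZR and MMP2 each had 13 reads or fewer.

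Of 33 lists with at least 3 tested genes, camera called 0. The smallest adjusted p was 0.838 with the preset correlation and 0.864 with an estimated correlation; 0 lists had an unadjusted p under 0.05 in camera, and 3 did in fry. In every list 0 members passed the threshold over all genes. Adjusted over the list alone, the counts in limma were 0 except for TNFRSF11B above and KRT18, the only tested epithelial gene, with 0 and 6 reads. The KRT18 call was lost without any library but shFTO replicate 2, at limma adjusted p values from 0.0748 to 0.171. The log2 fold change of KRT18 was 2.245 as reported and without each shNC library. It was 1.693 and 1.675 without shFTO replicates 1 and 3. The call was also lost with a pseudocount of 0.1, no filter and at least 5 CPM (limma adjusted p = 0.0788, 0.0835 and 0.0502). In the fit to recovered reads the counts over the list alone were 0 except for HNRNPA2B1 and for ALDH1A3, the only stemness gene with enough reads, with 26 and 8 reads, 19 of the 26 in shNC replicate 1.

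In 3 of the 36 lists with reads, the summed reads of the 2 groups did not overlap, where chance gives 10%: the m6A list above, autophagy and lysosome, and NRF2 targets and ferroptosis regulators. The autophagy and lysosome list had 128 ± 5.48 of 100000 reads in shNC and 154 ± 7.01 in shFTO (exact two-sided permutation p = 0.1, adjusted p = 0.847 over 36 lists), with CTSA, encoding a lysosomal protease, at 86.3 ± 3.55 and 108 ± 5.51 FPKM. CTSA held 499 of its 840 reads, and without CTSA the list had 54 ± 2.9 and 61 ± 10.4 (exact p = 0.4). The NRF2 and ferroptosis list had 131 ± 14.9 and 105 ± 5.99 of 100000 reads (exact p = 0.1), with SAT1, encoding a polyamine acetyltransferase, at 265 ± 43.9 and 208 ± 30.2 FPKM. Without SAT1 it had 65.4 ± 4.32 and 53.4 ± 4.05 (exact p = 0.1). With the most-read gene of each list left out, the groups did not overlap in 5 of 35 lists, where chance gives 10%. Ratios of shFTO to shNC were 1.21 for the osteoblast lineage, 1.15 for collagen and basement membrane genes and 1.02 for splicing factors. They were 0.898 for G2 and M-phase genes and 0.818 for NRF2 and ferroptosis genes. The ATF4 amino acid response had 53.3 ± 6.85 and 69.7 ± 9.75 of 100000 reads (exact p = 0.2), in which the amino acid transporter gene SLC38A2 had 41.6 ± 11.2 and 54 ± 2.13 FPKM. In the endoplasmic reticulum stress list, whose reads had a ratio of shFTO to shNC of 1.02, the chaperone gene HSPA5 had 29 ± 4.42 and 13 ± 1.53 FPKM (limma adjusted p = 0.772). Among inflammatory genes, with a ratio of 0.973, or 1.33 without CXCL8, the chemokine gene CXCL8 had 72.7 ± 24.4 and 44.1 ± 22.3 FPKM and the cyclooxygenase gene PTGS2 had 8.8 ± 6.11 and 21.1 ± 6.61.

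In the signalling lists 0 members were called. TGF-beta targets had a read ratio of 1.02, and within them the matricellular gene CCN2 had 63.6 ± 31.6 and 86.7 ± 16.3 FPKM, while TGFBR2, the type II receptor gene of TGF-beta, had 12 reads in shNC and 0 in shFTO. With shFTO set at 3 reads over the group and the 12 shNC reads taken as exact, TGFBR2 would be 4.21-fold lower, not a lower bound. Its limma adjusted p was 0.772, and limma-voom on recovered reads called it, with a log2 fold change of -3.19 (adjusted p = 0.00313). YAP and TAZ targets had a ratio of 1.07, WNT targets and inhibitors 0.857, growth factor receptor and MAPK feedback genes 0.735, immediate early genes 1, and PI3K, AKT and mTOR pathway genes 0.96. In these lists the receptor gene MET had 13 and 1 reads, DUSP1, a phosphatase of MAP kinases, had 8 and 2, and RICTOR, a subunit of mTOR complex 2, had 8 and 0. Of the 8 RICTOR reads 6 were in shNC replicate 2, which leaves 2 without it. Hypoxia genes had a ratio of 0.912 and type I interferon genes 1.16 on 40 reads in all. Stemness factors had a ratio of 0.663, carried by ALDH1A3, without which the list had 29 and 31 reads. For the summed reads of these whole signalling, hypoxia, interferon and stemness lists, exact two-sided permutation p values ran from 0.2 to 0.9.

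Cell cycle and survival lists gave 0 calls among 20 S-phase, 31 G2 and M-phase, 11 p53 target and 8 BCL2 and caspase genes tested. The S-phase list had 99 reads in all and a ratio of 0.987, and the G2 and M-phase list had a ratio of 0.918, with ANP32E at 13 and 6 reads. The p53 target list had a ratio of 1.03 and the BCL2 and caspase list 0.985. BAX, which permeabilises mitochondria in apoptosis, belonged to both and had 0 and 5 reads, all 5 in shFTO replicate 1, which leaves 0 and 0 without that library. Metabolic lists gave ratios of 0.895 for glycolysis, 1.22 for nuclear-encoded oxidative phosphorylation, 0.816 for sterol biosynthesis and 0.967 for fatty acid synthesis and storage. For the summed reads of these whole cell cycle, survival and metabolic lists, no exact two-sided permutation p was below 0.3. HMGCS1, an early enzyme of sterol synthesis, had 17 and 2 reads, 11 of the 17 in shNC replicate 2, and ATP5F1B, a subunit of ATP synthase, had 16 and 27. Muscle, epithelial and neural marker lists held 33, 8 and 19 reads in all, and replication-dependent histones had none.

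**Figure D3:**
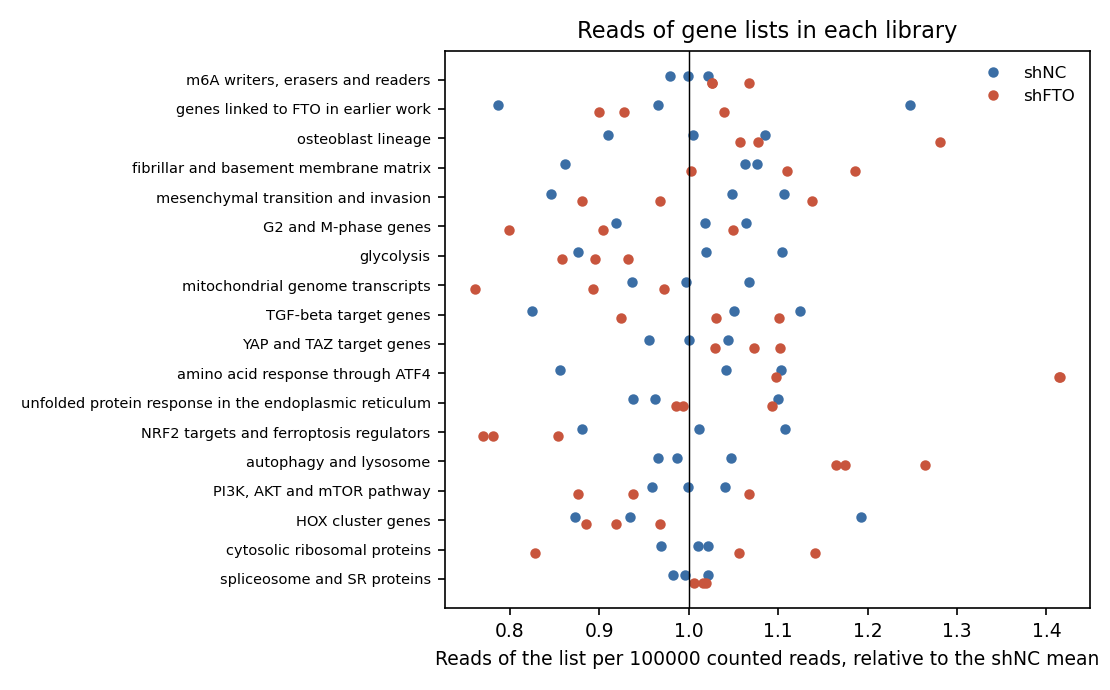
Reads of each gene list per 100000 counted reads in each library, divided by the mean of the 3 shNC libraries, for the 18 lists with at least 300 reads in all. Points are libraries; the 3 shFTO points lie above the 3 shNC points for the m6A list and for autophagy and lysosome, and below them for NRF2 targets and ferroptosis regulators.

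The splicing, ribosomal and mitochondrial lists gave 0 calls in the reported fit, which does not show that the groups were alike. MT-ND6 was called without shFTO replicate 2. MT-ND3 was called without shNC replicate 2 and with the replicate block. The splicing factor list held 4453 ± 88.9 of 100000 reads in shNC and 4515 ± 30.3 in shFTO. Without HNRNPK, its most-read gene, it had 3714 ± 51.15 and 3776 ± 8.82 (exact two-sided permutation p = 0.1). SRSF2 had 839 ± 48.3 and 975 ± 76.8 FPKM (limma adjusted p = 0.772). The 50 ribosomal protein genes held 0.716 ± 0.0198% and 0.723 ± 0.116% of reads (exact two-sided permutation p = 1). The 13 mitochondrial protein genes held 0.234 ± 0.0153% and 0.205 ± 0.025% (exact p = 0.2), with MT-CO1 at 405 ± 33.8 and 342 ± 46.8 FPKM. The 10 genes with the most reads held 32 ± 0.235% and 31.6 ± 0.579% (exact p = 0.4). Genes with at least 1 read numbered 3314 ± 96 in shNC and 3431 ± 4.04 in shFTO (exact p = 0.1). Reads came to 96320 ± 4059 and 101300 ± 6372 (exact p = 0.3), while shFTO replicate 2, with 94083 reads, had more genes above 0 than shNC replicate 2, with 100992 reads (3427 against 3395). No exact test of 3 against 3 can go below 0.1.

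Libraries of one group differed from each other about as much as libraries of different groups. The chi-square per degree of freedom over genes with at least 10 reads in a pair averaged 1.86 in the 6 pairs within groups (1.73 to 1.97) and 1.89 in the 9 pairs between groups (1.73 to 2.03). Of the 10 splits of the libraries into 3 and 3, 3 had a difference between these means at least as large as the real one (exact one-sided permutation p = 0.3). Every pair differed by more than counting error.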

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

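The alternatives with median-of-ratios, upper-quartile and 10-read settings and the quasi-Poisson fit were chosen after seeing the data; the others were planned. The count of called genes, 2 as reported and the same past 2-fold, was 7 with a pseudocount of 0.1 (5 higher and 2 lower), 9 with no filter (7 higher and 2 lower), 1 with a mean of at least 5 CPM, 1 at an adjusted p under 0.01 and 1 against a 1.2-fold change. It was 2 with median-of-ratios scaling, 4 with upper-quartile scaling, 0 with at least 10 reads per library and 0 in the quasi-Poisson fit, the last 2 on 705 and 1021 genes. Limma-voom called 5 genes (ANKLE2, C5orf24, CAV1, RARS1 and TGFBR2), 0 of them shared with the reported 2. Leaving out 1 library gave 2 to 9 genes. Except where fewer genes or libraries were tested, the cause was not tested. Upper-quartile scaling moved the median log2 change of genes with reads in all 6 libraries to 0.12, from 0.02.

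With the replicate number as a block, 17 genes were called, 13 higher and 4 lower, and 17 past 2-fold. Deviations of same-numbered libraries from their group means correlated at -0.00292, 0.0392 and -0.0116 over 705 genes. In 1 of 3 pairs both libraries correlated best with their own number. Correlations this low do not exclude a shared day or batch, since counting error in genes with few reads could hide one.

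ENSAP2 and H3P47 were not called in limma-voom, nor H3P47 with at least 5 CPM. Of 1201 combinations of named gene and alternative, 1179 kept direction and side of the threshold, and 9 changed sign, none of them called. Only 2 of the 91 named genes were past the threshold in the reported fit, so most could hardly change side. With no filter, the CPM minimum or the replicate block, the fold change stays the same by construction. The count of 1179 thus says little about robustness. Leaving out 1 library gave IFIT1 -0.83 to 0.030, SMTN -0.41 to 0.54, ACTA2 -0.73 to 0.69 and NCAM1 -0.12 to 0.58, with the cause not tested. RPS12, with 1 and 8 reads, was called with a pseudocount of 0.1, no filter, the block and without shNC replicate 3.

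Camera, fry and all list alternatives called 0 lists, with a smallest adjusted p of 0.1 on genes with at least 10 reads. The difference between groups in each share of reads moved by less than 1 SD with protein-coding genes as denominator or without mitochondrial transcripts. Protein-coding genes held 98% of reads, and mitochondrial transcripts 0.234% in shNC and 0.205% in shFTO. These denominators could therefore hardly move a share, and the result says little about robustness. FTO, at 0, had no value under any alternative. Planned fits with other count tools were not run; the recovered reads were tested with limma-voom and the quasi-Poisson fit. Without the most-read gene, chosen after seeing the data, list ratios moved from 0.987 to 1.19 for S-phase genes, from 0.985 to 1.21 for BCL2 and caspase genes and from 0.967 to 1.15 for fatty acid genes. Depth limits single genes: 4331 of 7057 genes with reads had 5 or fewer over the 6 libraries.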

Other observations

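The tests of strand, of pseudogene copies and of counting error were chosen after the result was seen; the splits of the libraries were planned. HOX genes, which mark position along the body axis, were read from the B, C and D clusters more than from A. HOXC6 had 157 reads over the 6 libraries, HOXC4 had 116, HOXB6 had 106 and HOXD10 had 61, while the highest HOXA gene, HOXA10, had 4. Per library these were 66.1 ± 6.48 FPKM in shNC and 87.5 ± 22.7 in shFTO for HOXC6, and 78.1 ± 13.1 and 59.1 ± 8.37 for HOXB6 (SD, n = 3 each). The list of 35 HOX genes had a read ratio of shFTO to shNC of 0.924. In limma 0 of 17 tested HOX genes were called, against 2 of all 4932 genes tested, and the quasi-Poisson fit called 0 of 1021 genes.

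Some pseudogenes had high FPKM values, in part because they are short. HNRNPA3P6 had 3327 FPKM on average over the 6 libraries, LSM12P1 had 2256 and EIF2S2P4 had 1038, against 140.5 for EEF1A1 and 6.79 for PPIA, a common reference gene. In reads over the 6 libraries these were 1979, 786, 609, 841 and 27. Pseudogenes held 1.7% of reads and protein-coding genes 98%.

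Most genes were listed at 0, while 34 genes held 50% of the reads over the 6 libraries. Counting on the opposite strand is argued against by MT-ND6, the protein gene on the other mitochondrial strand, with 1.24% of the reads of the 13 mitochondrial protein genes (exact 95% interval 0.707% to 2%). For loss of reads shared with pseudogenes, protein-coding genes with a processed pseudogene named after them were compared with those without one. Of these, 33.7% and 70.3% were at 0 in all 6 libraries (odds ratio 0.215, 95% interval 0.194 to 0.239). The sets were not matched by expression, and 11.3% of the first had at least 10 reads per library on average, against 2.65% of the second. The comparison therefore cannot decide whether such loss is the whole cause. Loss of all or part of the reads of such genes stays open, and so does an origin of reads in another organism, which was not tested. The reads themselves were not analysed here, and no biological explanation was tested, since the pattern is in both groups. Low depth leaves the expected shares of genes as they are, but it can leave genes with small shares at 0. Of 7057 genes with reads, 4331 had 5 or fewer over the 6 libraries and 2673 had reads in 1 library only. How many of the genes at 0 are due to depth was not tested.

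Whether the calls of ENSAP2 and H3P47 may come from counting error of a few reads stays open. In the simulated data, limma gave 2.4, 2.8 and 6.2 false calls per simulation with genes changed 2-fold, 4-fold and 8-fold. Each simulation held 200 changed genes, so the number of false calls in the real data is not known from it. The 2 calls reported are no more than the false calls per simulation, which gives no ground to take either ENSAP2 or H3P47 as a true change. Exact two-sided binomial tests of their summed reads gave p = 0.0275 for ENSAP2 and p = 0.0314 for H3P47, but so few reads could not pass 0.05 divided by the 4932 genes tested however they fell, the smallest possible p being 0.0275 and 4.28e-05. Related coding genes were read in both groups, ENSA with 16 and 11 reads and, among histone H3 genes, H3-3A with 76 and 67 and H3-3B with 1890 and 2202, and reads shared with them could not be told from the table. An effect of FTO knockdown on these transcripts is untested beyond these reads.

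Other splits of the 6 libraries into 3 and 3 were fitted in the same way. Of the 10 splits, 5 gave at least the 2 genes of the real split, and the highest of the others gave 6. Past 2-fold, 4 of the 10 splits gave at least 2 genes, with 6 in the highest of the others. The real split called 0 gene lists, a count that all 10 splits must reach, so the splits do not bear on it; the highest of the others also called 0. Splits this few cannot give a share under 0.05.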
